A study of Ambystoma mexicanum with 27 samples.

How the data were processed

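RNA sequencing was used on cells of axolotl limbs (Ambystoma mexicanum) taken on the day of amputation and 4 or 5 days later (0, 4 and 5 dpa, days post-amputation). At each time point 3 cell fractions were taken. Stump tissue was dissociated with collagenase and dispase, stained with DAPI and sorted by DNA content into a 2N and a 4N fraction, and skin was dissociated with trypsin and EDTA. The epidermal fraction is normal epidermis at 0 dpa and wound epidermis at 4 and 5 dpa. Each of the 9 groups held 3 replicates, which gave 27 libraries. RNA was recovered with a total nucleic acid kit, amplified and turned into libraries, which were sequenced on both a NextSeq and a HiSeq instrument, per the labels. The labels give no batch, date or instrument for a single library, so no batch could be tested. No source states that replicates came from separate animals, so p-values measure the spread between these samples.

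The authors quantified transcripts of an assembled transcriptome with kallisto, whose version the labels do not give. The deposited expression matrix holds a signal for each transcript and library, which is the TPM (transcript abundance scaled to a fixed total) rescaled by the authors with 1 trimmed-mean (TMM) factor per library. It lists 1554055 transcripts, of which 1410405 were above 0 in any library and 112281 in all 27. Because these values are rescaled TPM, read depth is unknown, and no counting interval or limit for a value of 0 can be given. The sum of the values per library ran from 895550 to 1032465. The number of transcripts above 0, used here as the sign of how much of the transcriptome a library caught, ran from 383655 to 955806.

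The authors also deposited 9 tables of differentially expressed transcripts made with DESeq2, version not given. Per the file headers they hold a log2 fold change, written so that a negative value is higher after amputation (or in 4N cells in the table of dividing cells), and an adjusted p-value. The deposited tables hold only adjusted p-values under 0.05, and the dividing-cell table lists only transcripts with a blastx hit. These tables name 26997 transcripts and give the only protein names in the files, as the best blastx hit to Swiss-Prot, and 6 broken lines were skipped. In this way 8495 transcripts carried a protein name, with 5245 distinct gene names. A gene name is therefore the best hit of an axolotl transcript, and a transcript has a name only if the authors called it there. The genes that can be named are for this reason a selection made on the same samples, and the direction of a named gene is not independent evidence.

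All values reported here were computed from the deposited matrix with R 4.3.3, limma 3.58.1 and data.table (version 1.17.8), except where the authors' deposited table is named, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Transcripts with a value of at least 1 in at least 3 of the 27 libraries were kept, which left 462698, of which 2882 had a name and stood for 1838 genes. A pseudocount of 1 was added and the log2 taken. One limma model with a mean for each of the 9 groups was fitted to all libraries, with the prior variance allowed to follow the mean. Each of 16 contrasts was tested with limma's moderated statistic, two-sided, with the Benjamini-Hochberg adjustment over all transcripts tested, and a transcript was called at an adjusted p of 0.05. Fold changes are ratios of values to which the pseudocount had been added, and their errors are standard errors (SE) of the log2 change; group means are given with the standard deviation (SD) over the 3 replicates. The contrasts were each later day against 0 dpa and 5 against 4 dpa in each fraction, 4N against 2N cells at each day, 4N cells against epidermis at 4 and 5 dpa, and the difference between the 4N and the 2N change since 0 dpa. Transcripts called in more than 1 contrast were counted for 2 questions: higher in 4N cells than in both other fractions (called in both, with a log2 difference of at least 1), and changed the same way in all 3 fractions. Chance expectations for these overlaps assume independent calls.

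Named genes were taken by a rule fixed before the data were examined. For each contrast it took the 10 genes with the largest rise and the 10 with the largest fall among called transcripts with a name, with all 3 replicates of 1 group above all 3 of the other and a mean of at least 10 in the higher group. It kept the transcript with the highest mean for each name and skipped hits to transposons and uncharacterized proteins. It added MKI67, TOP2A, PCNA, CXCL8, IL1B, PRRX1, KAZALD1, MDK, CSF1R, KRT5 and COL1A1 whatever their result, and up to 4 called members of a gene list with the smallest adjusted p. MMP9 and ACTA1 were in the rule but have no named transcript in the files.

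In the same way 20 gene lists were fixed before the data were examined: DNA replication, mitosis and G2/M, histones and chromatin proteins, cytosolic ribosome, mitochondrially encoded genes, extracellular matrix, matrix proteases and inhibitors, cytokines and inflammation, interferon response, growth factor signalling, limb development and blastema, immediate early and heat shock genes (a sign of dissociation), and markers of epidermis, myeloid and other leukocytes, lymphocytes, erythrocytes, cartilage and bone, Schwann cells and nerve, endothelium, and skeletal muscle. Lists with at least 3 measured members, 18 of the 20, were tested with camera (limma) at a preset correlation of 0.01, with the other named genes as the background and the adjustment within each contrast. The test was repeated with a correlation estimated from the data, and 0 of the 288 list tests passed with it.

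The test was tried on simulated data, in which each transcript had its mean of the 2N libraries of 0 dpa and its residual spread, with known changes added at 4 dpa to abundant transcripts. Of 50 transcripts changed by a log2 of 1 it recovered 20%, and of 50 each at 2, 3 and 4 it recovered 86%, 90% and 100%. The sign was right in each recovered transcript, and 10 unchanged transcripts were called. Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, rescaling by median-of-ratios factors, the replicate number as a block, only the groups compared in the model, values summed over the transcripts of 1 gene, and each replicate left out in turn; where this left a group with fewer libraries, the model takes their spread to be that of the other groups. Chosen after seeing the data were a filter of at least 5 in at least 3 libraries, limma array weights, and leaving out the 3 libraries with the fewest transcripts above 0, or only the 4N libraries among them. Groups were also formed by other splits of the same libraries, all 10 where there were 10 and 100 draws where there were more.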

Results

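The axolotl, a salamander, regrows an amputated limb from cells that gather under a wound epidermis. The study set out to find transcripts that change in, and are enriched in, the cells that divide early. RNA was measured in 27 libraries, 3 for each of 9 groups: stump cells with 2N DNA content, stump cells with 4N DNA content (cells that have copied their DNA) and epidermis, each at 0, 4 and 5 dpa. In these libraries 383655 to 955806 transcripts had a signal above 0. The epidermis library of 5 dpa replicate 3 had 383655. The 4N libraries of 0 dpa replicates 2 and 3 had 410899 and 510210, and all others had at least 660025. The first 3 are called the sparse libraries below. Pearson's r of log2 signal across transcripts, which are not independent replicates, was 0.473 to 0.528 between the 4N replicates of 0 dpa, 0.568 to 0.774 between those of the 5 dpa epidermis, and 0.654 to 0.796 within the other groups.

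A set of 18 transcripts that were abundant in the epidermis at every day and scarce in both stump fractions at 5 dpa served as a measure of epidermal RNA in stump libraries. Their median level, as a percentage of that in 0 dpa epidermis, was 42.6%, 4.36% and 9.0% in 4N replicates 1, 2 and 3 of 0 dpa and 10.3%, 5.32% and 3.7% in the 2N replicates of 0 dpa. Their choice sets a low level at 5 dpa, so no fall since 0 dpa is read from them.

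**Figure D1:**
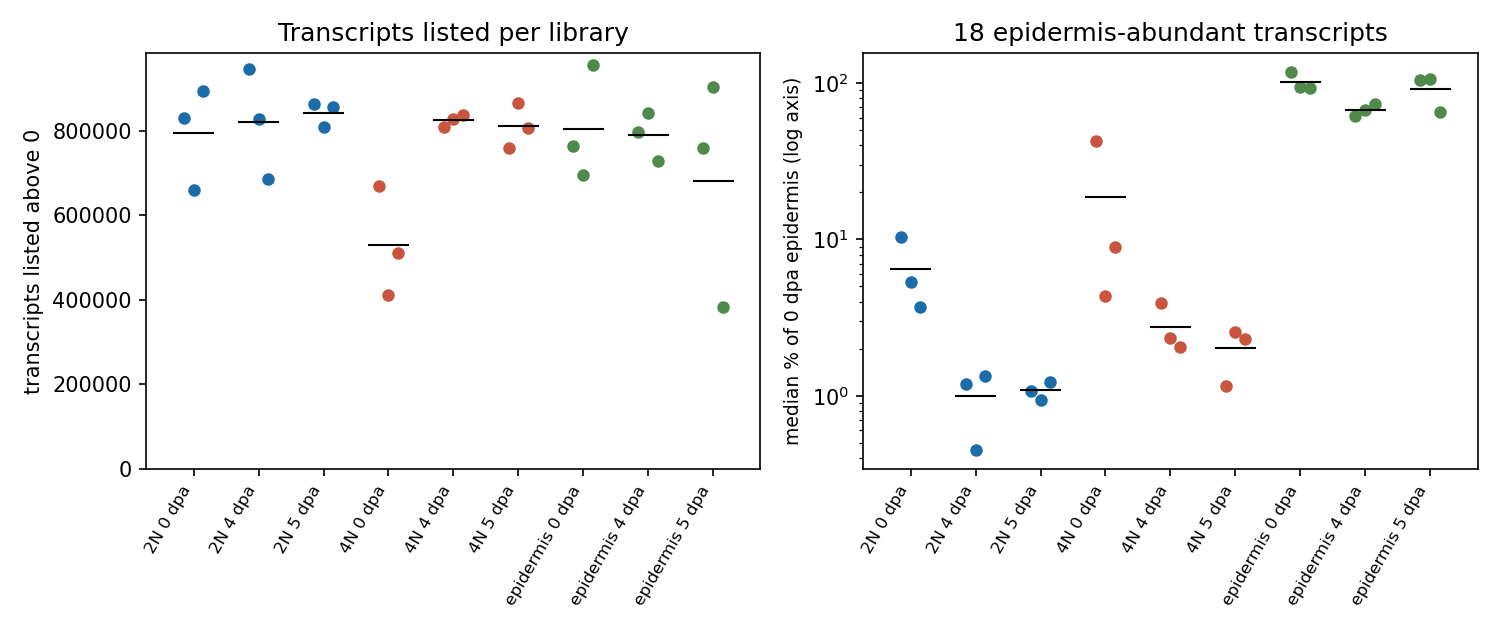
Transcripts with a signal above 0 per library (left) and the median level of 18 epidermis-abundant transcripts as a percentage of their mean in 0 dpa epidermis (right, log axis, transcripts chosen to be scarce in stump cells at 5 dpa), by group; points are the 27 libraries and bars are group means. The lowest number is 383655 in the epidermis at 5 dpa, and the highest percentage in a stump library is 42.6% in 4N cells of 0 dpa.

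Values of a gene below are the mean signal ± SD of the later or first-named group against that of the other, n = 3 libraries each, and log2 changes are given ± SE from limma. In each gene given as risen, fallen, higher or lower, all 3 libraries of one group lay above all 3 of the other, except for the difference between fractions in their change, where no such order can be given. Members of the gene lists are preselected, because a transcript has a name here only if the authors' deposited tables list it as changed in these samples, so the counts per list are not independent evidence of their direction. The adjusted p of a list is that of camera with the preset correlation, and with the estimated correlation 0 of the 288 list tests passed.

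The first comparisons asked what changed in 2N stump cells after amputation. At 4 dpa the signal of PLBL1, a phospholipase B-like enzyme, was 93.5±25.3 against 0.956±0.534 (48.2-fold, log2 change 5.59±0.47, adjusted p = 2.16e-06). CAMP, an antimicrobial peptide, rose to 12.5±6.64 against 0.109±0.0608 (log2 change 3.48±0.41, adjusted p = 4.18e-05). LYZ, the lysozyme of leukocyte granules, rose 10.8-fold (log2 change 3.44±0.43, adjusted p = 8.13e-05). COL1A1, the main chain of type I collagen, had 34.5±15.1 against 265±54.9 (log2 change -2.97±0.35, adjusted p = 4.18e-05).

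Among 30 markers of myeloid and other leukocytes, 13 rose, 1 fell and 16 were not called (25 rose and 2 fell when adjusted over the list alone, adjusted p = 1.49e-06). Of 35 extracellular matrix genes 25 fell, 0 rose (3 at an unadjusted p under 0.05) and 10 were not called (30 fell and 3 rose adjusted over the list alone, adjusted p = 6.93e-11). Cytokine and inflammation genes rose in 7 of 14 members and fell in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.00513). The interferon response list had 5 of 17 members higher (8 adjusted over the list alone) (adjusted p = 0.00513). Of 22 matrix proteases and inhibitors 10 rose and 4 fell (13 and 5 adjusted over the list alone, adjusted p = 0.232). MMP2 (3.33±0.38) and MMP18 (3.25±0.37) rose and ADAMTS5 (-1.54±0.22) fell. Of 6 mitochondrially encoded genes 4 rose, and 6 adjusted over the list alone, with MT-ATP6 at 1.97±0.22 (adjusted p = 0.00904). Of these counts, those that moved by over 1.5 times without 1 library were leukocytes rising 7 (0 dpa replicate 2) or 8 (4 dpa replicates 2 and 3), cytokines rising 3 or 4 (any but 4 dpa replicate 1), interferon genes rising 2 (0 dpa replicates 1 and 2 and 4 dpa replicates 1 and 3), and proteases rising 6 (4 dpa replicate 3).

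Epidermal markers fell in 3 and rose in 2 of 33 members (6 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.131). The basal keratin KRT5 had 2.17±1.24 against 33±18 (log2 change -3.35±0.48, adjusted p = 0.000298) and KRT15 -2.67±0.39. The epidermis-abundant set stood at 3.70% to 10.3% of the epidermal level in the 0 dpa libraries. All 6 erythrocyte genes were lower only when adjusted over the list alone, with 0 called by limma over all transcripts (6 at an unadjusted p under 0.05). Their median log2 change was -1.66 (adjusted p = 0.0387, and adjusted p = 0.0821 with array weights). Immediate early and heat shock genes, a sign of dissociation, rose in 4 of 13 (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.252). The heme oxygenase HMOX1 was at 2.84±0.40 and the chaperone HSPA5 at 1.90±0.36. No list call was made for cartilage and bone (median -0.65), growth factor signalling (-0.47), limb development and blastema (-0.56), Schwann cells and nerve (-0.45), lymphocytes (-0.78), cytosolic ribosome (-0.28), DNA replication (0.12), mitosis and G2/M (0.12) or histones and chromatin proteins (0.22). Their adjusted p ran from 0.179 to 0.753. Endothelium and skeletal muscle had 2 measured members each and were not tested as lists. VWF had a log2 change of -0.49±0.27, LYVE1 -0.30±0.21, TTN -0.82±0.29 and TPM1 -1.03±0.29, none of them called. Of the proliferation genes, MKI67 (-0.45±0.30, adjusted p = 0.632), PCNA (-0.49±0.43, adjusted p = 0.762) and TOP2A (0.03±0.31, adjusted p = 0.996) were not called in 2N cells. Nor were IL1B (0.77±0.33, adjusted p = 0.328), CSF1R, a receptor of macrophages (0.76±0.29, 0.252), PRRX1 (-0.52±0.27, 0.475), KAZALD1 (0.96±0.35, 0.209) and MDK (-0.47±0.43, 0.769).

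In all, limma called 7283 transcripts at 4 dpa in 2N cells, 3828 higher and 3455 lower, which stand for 378 named genes. Without 1 library the count was 4571 or 3433 (0 dpa replicates 1 and 2), 4112, 4594 or 3757 (4 dpa replicates 1, 2 and 3). With only these 6 libraries in the model limma called 40, and 52533 had an unadjusted p under 0.05, against 54246 with all 27.

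At 5 dpa in 2N cells the matrix metalloproteinases MMP2 and MMP18 had 24.8±12.5 against 0.319±0.0958 and 20.7±9.34 against 0.265±0.0805 (log2 change 4.17±0.38, adjusted p = 4.86e-06, and log2 change 3.99±0.37, adjusted p = 4.86e-06). PLBL1 rose 47.3-fold (log2 change 5.57±0.47, adjusted p = 2.38e-06). TENX, a tenascin of the matrix, had 4.21±1.63 against 48±9.72 (log2 change -3.26±0.38, adjusted p = 6.47e-05), and COL1A1 55.2±8.96 against 265±54.9 (log2 change -2.23±0.35, adjusted p = 0.00102). Leukocyte markers rose in 9 of 30 members and fell in 0 (2 at an unadjusted p under 0.05), against 26 and 2 adjusted over the list alone (adjusted p = 3.11e-07). Matrix genes fell in 25 of 35 members, 1 rose and 9 were not called (28 fell and 2 rose adjusted over the list alone, adjusted p = 1.07e-09). The cytokine list had 6 of 14 members higher and 1 lower (adjusted p = 0.0113). The interferon list had 1 of 17 higher, with 7 adjusted over the list alone (adjusted p = 0.0183), and the mitochondrial list 4 of 6 higher (adjusted p = 0.0072).

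Epidermal markers fell in 3 and rose in 1 of 33 members at 5 dpa in 2N cells, with KRT5 at -2.71±0.48 and KRT19 at -1.75±0.30 (adjusted p = 0.0489). Erythrocyte genes had a median log2 change of -1.73, and 1 of 6 was called lower (6 adjusted over the list alone, adjusted p = 0.0183). List counts that moved so far without 1 library were leukocytes rising 4 (5 dpa replicate 3) or 5 (0 dpa replicate 2), cytokines rising 2 or 3 (any but 0 dpa replicate 1), interferon genes rising 0 (any library), and erythrocyte genes falling 0 (0 dpa replicate 2 and 5 dpa replicates 2 and 3) or 2 (5 dpa replicate 1). Limma called 3910 transcripts, 1913 higher and 1997 lower (288 named genes). Without 1 library the count was 2427 or 1705 (0 dpa replicates 1 and 2), 2128, 1812 or 1684 (5 dpa replicates 1, 2 and 3). With only these 6 libraries in the model limma called 0, with 51822 at an unadjusted p under 0.05.

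The same question was put to 4N stump cells, the fraction that holds dividing cells. At 4 dpa TNC, a tenascin laid down in healing tissue, had 21.8±6.0 against 0.65±0.608 (14.1-fold, log2 change 3.81±0.43, adjusted p = 4.48e-05). KAZALD1, a secreted protein with a Kazal-type inhibitor domain, had 7.93±2.97 against 0.0423±0.0451 (log2 change 3.05±0.35, adjusted p = 5.1e-05). The cytokine IL11 rose to 3.68±1.58 against 0.0203±0.0153 (log2 change 2.14±0.31, adjusted p = 0.000679), and CXCL8, which attracts neutrophils, rose 5.89-fold (log2 change 2.56±0.42, adjusted p = 0.00209). The collagenases MMP13 and MMP18 rose 6.65-fold and 7.58-fold (log2 change 2.73±0.50, adjusted p = 0.00529, and log2 change 2.92±0.37, adjusted p = 0.000149). PLBL1 rose 16-fold, and CTSS, a cathepsin of antigen-presenting cells, fell (log2 change -1.78±0.32, adjusted p = 0.00402). Of the 3 control libraries, replicates 2 and 3 were the 4N libraries of 0 dpa with 410899 and 510210 transcripts above 0. Calls that end or appear without the 3 sparse libraries are given with their p. The one 0 dpa control then left is replicate 1, at 42.6% of the epidermal level, and epidermal RNA in it alone would make matrix genes appear to rise.

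Proteases and inhibitors rose in 9 of 22 members and fell in 0 (3 at an unadjusted p under 0.05), against 12 and 2 adjusted over the list alone (adjusted p = 0.000333). Cytokine genes rose in 3 of 14 members and fell in 0 (2 at an unadjusted p under 0.05), against 5 and 2 adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.176 without the 3 libraries). Of the mitochondrial genes 4 of 6 rose (6 adjusted over the list alone), with MT-ATP6 at 1.65±0.22 (adjusted p = 0.00136). The leukocyte list had 2 of 30 members higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0177). Among matrix genes 3 of 35 rose and 7 fell (7 and 13 adjusted over the list alone), and the list was not called (adjusted p = 0.141), but was higher without the 3 libraries (adjusted p = 0.00723). Not called with all libraries but called without them were also growth factor signalling (higher, adjusted p = 0.0235), cytosolic ribosome (lower, 0.0225) and limb development (higher, 0.0481). The median log2 change of interferon genes was 0.39, with 0 of 17 members called by limma (6 at an unadjusted p under 0.05) and 5 higher adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.105 without the 3 libraries).

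Epidermal markers fell in 4 and rose in 1 of 33 members in 4N cells at 4 dpa (13 and 5 adjusted over the list alone, adjusted p = 0.0199). KRT5 had 7.96±2.34 against 108±117 (log2 change -3.08±0.48, adjusted p = 0.0013). Its 3 control libraries stood at 243, 44.3 and 35.5, where the epidermis-abundant set stood at 42.6%, 4.36% and 9.0% of the epidermal level. Erythrocyte genes had a median of -1.67 with 0 called by limma (6 at an unadjusted p under 0.05) and 6 of 6 members lower adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.264 without the 3 libraries). MKI67 (-0.30±0.30), PCNA (-0.09±0.43) and TOP2A (-0.58±0.31) were not called. The 4N list counts that moved by over 1.5 times without 1 library were proteases rising 3 (4 dpa replicate 3), leukocytes rising 0 (4 dpa replicate 3) or 1 (0 dpa replicates 2 and 3 and 4 dpa replicate 2), matrix genes falling 2 or 14 (any but 4 dpa replicate 3), epidermal markers falling 2 (0 dpa replicate 1 and 4 dpa replicates 2 and 3) or 7 (0 dpa replicate 3), and erythrocyte genes falling 1 (0 dpa replicate 1) or 3 (0 dpa replicate 3).

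Limma called 7236 transcripts at 4 dpa in 4N cells, 5860 higher and 1376 lower, so that 81% were rises (150 named genes). The model takes a common spread for all groups. The 4N libraries of 0 dpa varied more than most, with array weights of 0.528, 0.389 and 0.502. Adjusted p in any comparison with them can be too small, and array weights gave far fewer calls. The authors' deposited table for this comparison has 3283 higher and 2529 lower. The share of rises was 70.7% with median-of-ratios rescaling. Without the 3 sparse libraries 6611 were called, 1773 higher and 4838 lower. Of these, 1081 rises and 358 falls were shared with the calls from all libraries. Without 1 library the count was 11629 (0 dpa replicate 1, 68.4% rises), 3151, 3488 or 4663 (4 dpa replicates 1, 2 and 3). The share of rises without 0 dpa replicates 2 or 3 was 58.5% and 62.8%. With only these 6 libraries in the model limma called 0, with 51281 at an unadjusted p under 0.05, against 71737 with all libraries.

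At 5 dpa in 4N cells KAZALD1 had 14±4.11 against 0.0423±0.0451 (14-fold, log2 change 3.81±0.35, adjusted p = 3.98e-06). TNC had 33.8±6.91 against 0.65±0.608 (21.7-fold, log2 change 4.44±0.43, adjusted p = 5.44e-06) and IL11 8.3±4.38 against 0.0203±0.0153 (log2 change 3.09±0.31, adjusted p = 9.65e-06). TIMP1, an inhibitor of metalloproteinases, rose 4.76-fold (log2 change 2.25±0.36, adjusted p = 0.00101), and INHBA, a chain of activin, 3.47-fold (log2 change 1.79±0.26, adjusted p = 0.000417). The keratins KRT5 and KRT15 fell (log2 change -3.15±0.48, adjusted p = 0.000671, and log2 change -2.41±0.39, adjusted p = 0.00132). The growth factor midkine, MDK, had 109±22.5 against 29.5±11.7 (log2 change 1.91±0.43, adjusted p = 0.0169). Its adjusted p was 0.0611 without 0 dpa replicate 1, 0.0845 without 5 dpa replicate 1 and 0.00688 to 0.259 over all alternatives. PRRX1, a transcription factor of limb mesenchyme, was not called (log2 change 0.52±0.27, adjusted p = 0.363).

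Of 22 proteases and inhibitors 10 rose and 0 fell (2 at an unadjusted p under 0.05), against 13 and 1 adjusted over the list alone (adjusted p = 3.4e-05). Growth factor signalling rose in 3 of 9 members (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.0107). The cytokine list had 3 of 14 members higher and 0 lower (1 at an unadjusted p under 0.05) and 4 higher adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.197 without the 3 sparse libraries). The mitochondrial list had 4 of 6 higher (adjusted p = 0.0027, and adjusted p = 0.124 without these). Epidermal markers fell in 7 of 33 and rose in 0 (0 at an unadjusted p under 0.05), with 15 lower adjusted over the list alone (adjusted p = 0.00142). The epidermis-abundant set stood at 4.36% to 42.6% of the epidermal level in the 0 dpa libraries. Erythrocyte genes fell in 5 of 6 members (6 adjusted over the list alone, adjusted p = 0.00255, and adjusted p = 0.127 without the 3 libraries). Matrix genes went both ways, 6 of 35 higher, such as THBS1 (1.80±0.31), and 4 lower, with 8 and 11 adjusted over the list alone (adjusted p = 0.763). Without the 3 libraries, and so against replicate 1 at 42.6% of the epidermal level alone, the matrix list was called higher (adjusted p = 5.5e-05), as were the ribosome (lower, 0.018) and limb development (higher, 0.018). With 1 library left out, counts that moved by over 1.5 times were proteases rising 5 (0 dpa replicate 2) or 6 (5 dpa replicate 3), epidermal markers falling 3 (0 dpa replicate 1 and 5 dpa replicates 1 and 2) or 4 (5 dpa replicate 3), erythrocyte genes falling 0 (0 dpa replicate 2 and 5 dpa replicate 2), 1 (5 dpa replicate 3) or 3 (5 dpa replicate 1), and matrix genes falling 1 (0 dpa replicate 2 and 5 dpa replicate 2), 2 (0 dpa replicate 3 and 5 dpa replicate 1) or 11 (0 dpa replicate 1).

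The count from limma at 5 dpa in 4N cells was 8967, with 7440 higher and 1527 lower, 83% of them rises, and 165 named genes. The authors' deposited table has 3614 higher and 2616 lower. Rises were 74.3% with median-of-ratios rescaling. When fitted without the 3 sparse libraries 2438 transcripts were higher and 5281 lower, and 1619 rises and 471 falls of these were shared with the calls from all libraries. With 1 library left out the count was 4033, 5822 or 5109 (5 dpa replicates 1, 2 and 3). The share of rises without 0 dpa replicate 1 was 70.4%. With only these 6 libraries in the model limma called 0, with 51410 at an unadjusted p under 0.05.

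**Figure D2:**
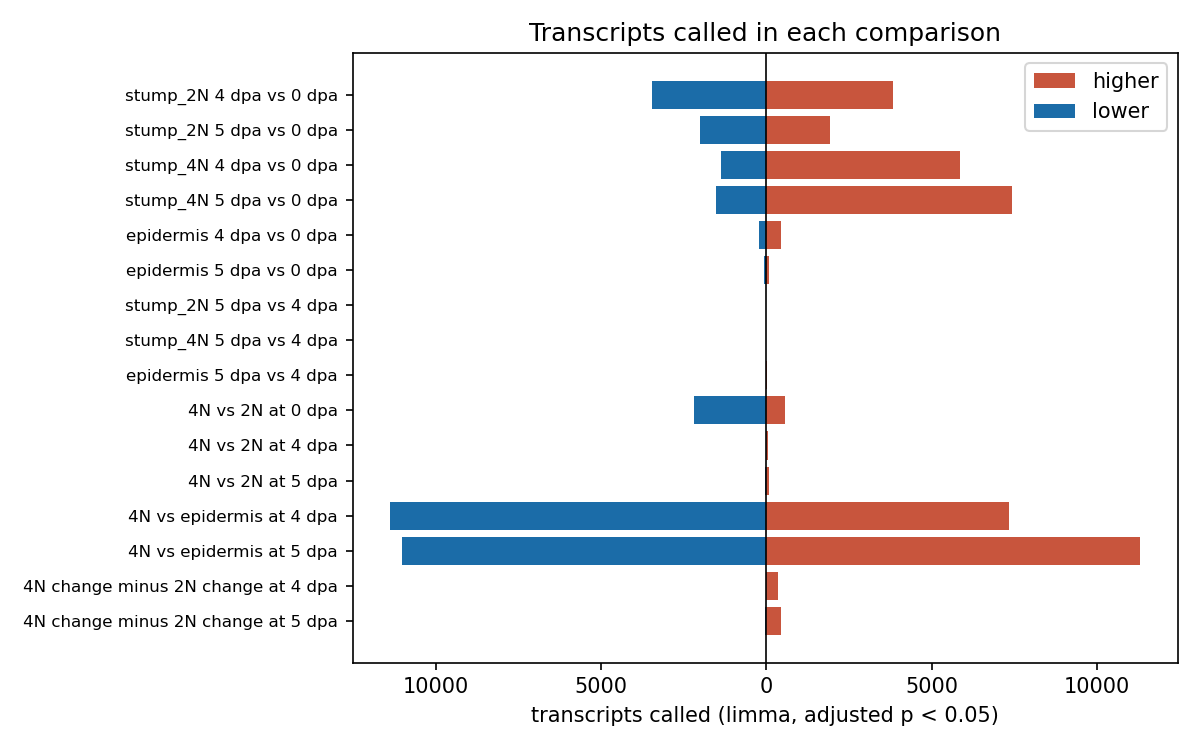
Transcripts called higher (right) and lower (left) by limma at an adjusted p of 0.05 in each of 16 comparisons. 4N cells have 5860 rises and 1376 falls at 4 dpa, a balance that is 1773 and 4838 without the 3 sparse libraries, and 2N cells have 3828 and 3455.

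The wound epidermis was compared with normal epidermis. At 4 dpa KRT6A and KRT17, keratins of activated epidermis, had 58.3±25.9 against 0.362±0.222 (41.2-fold, log2 change 5.36±0.35, adjusted p = 1.05e-08) and 19±9.72 against 0.463±0.446 (log2 change 3.67±0.35, adjusted p = 1.49e-05). KRT8, a keratin of simple epithelia, had 57.1±33.1 against 0.323±0.116 (log2 change 5.23±0.38, adjusted p = 5.5e-08). The chemokines CCL4 and CXCL10 rose to 5.19±2.68 against 0.158±0.037 and 13.2±9.27 against 0.675±0.376 (log2 change 2.32±0.31, adjusted p = 0.00143, and log2 change 2.92±0.41, adjusted p = 0.00185). PLBL1 rose 11.5-fold (log2 change 3.52±0.47, adjusted p = 0.00124). PCNA, the sliding clamp of DNA polymerase, had 25±6.07 against 3.54±2.88 (log2 change 2.67±0.43, adjusted p = 0.00648). Its adjusted p was 0.0709 without 0 dpa replicate 1, 0.0525 without 0 dpa replicate 2 and 0.0017 to 0.492 over all alternatives. Of 10 DNA replication genes 3 rose and 10 when adjusted over the list alone (adjusted p = 1.06e-06). The same counts were 1 and 13 of 15 mitosis genes (adjusted p = 1.06e-06) and 1 and 9 of 10 histones and chromatin proteins (adjusted p = 0.000189). Interferon genes rose in 3 of 17 members, 9 adjusted over the list alone (adjusted p = 0.00139). Ribosomal protein genes had a median of -0.87, with 0 of 21 members called by limma (15 at an unadjusted p under 0.05) and 1 lower adjusted over the list alone (adjusted p = 8.7e-06). Epidermal markers rose in 4 of 33 members (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.402), and KRT5 was not called (-0.79±0.48). Counts that moved by over 1.5 times without 1 library were DNA replication 0 (0 dpa replicates 1 and 2) or 1 (4 dpa replicate 2), mitosis 0 or 2 (any but 0 dpa replicate 3), histones and chromatin proteins 0 (0 dpa replicates 1 and 2 and 4 dpa replicates 1 and 2), and interferon genes 0 (0 dpa replicate 1) or 1 (4 dpa replicates 1 and 3). MKI67 (0.73±0.30, adjusted p = 0.578) and TOP2A (1.25±0.31, adjusted p = 0.127) were not called.

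Limma called 654 transcripts in the 4 dpa epidermis, 440 higher and 214 lower (47 named genes). With 1 library left out the count was 128 or 260 (0 dpa replicates 1 and 2), 230 or 295 (4 dpa replicates 1 and 3). With only these 6 libraries in the model limma called 0, with 35603 at an unadjusted p under 0.05.

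At 5 dpa the epidermis had KRT6A at 40.3±10.8 against 0.362±0.222 (log2 change 4.90±0.35, adjusted p = 8.26e-08), KRT8 at 28.3±4.46 against 0.323±0.116 (log2 change 4.46±0.38, adjusted p = 1.93e-06) and KRT17 at 18±2.15 against 0.463±0.446 (log2 change 3.73±0.35, adjusted p = 1.04e-05). MDK had 36.4±15.5 against 1.37±0.393 (14.7-fold, log2 change 3.88±0.43, adjusted p = 0.000144). FN1, the fibronectin of the provisional wound matrix, had 19.2±10.3 against 0.986±0.473 (9.2-fold, log2 change 3.20±0.40, adjusted p = 0.00077). Replicate 3 of this group had 383655 transcripts above 0. DNA replication genes had a median log2 change of 0.55, with 0 of 10 members called by limma (5 at an unadjusted p under 0.05) and 4 higher adjusted over the list alone (adjusted p = 0.000747). Mitosis genes had 0.73, with 0 of 15 called (12 at an unadjusted p under 0.05) and 10 higher adjusted over the list alone (adjusted p = 6.7e-06). The list of histones and chromatin proteins, which lacks H1, had 0.86, with 1 of 10 and 6 (adjusted p = 0.000194). The medians were 0.97 for interferon genes (9 of 17 higher adjusted over the list alone, adjusted p = 0.00193), -0.51 for the ribosome (adjusted p = 8.8e-05) and 0.40 for leukocytes (1 of 30 higher, adjusted p = 0.0318, and adjusted p = 0.177 without the 3 sparse libraries and 0.123 with array weights). List counts without 1 library moved to histones and chromatin proteins 0 or 2 (any but 5 dpa replicate 2), and leukocytes 0 (0 dpa replicate 1).

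Limma called 152 transcripts in the 5 dpa epidermis, 79 higher and 73 lower. The count was 124 without replicate 3 (94 higher and 30 lower, in a model that also leaves out both 4N libraries with few transcripts). With 1 library left out it was 49, 58 or 340 (0 dpa replicates 1, 2 and 3), 602 or 94 (5 dpa replicates 2 and 3). With only these 6 libraries limma called 0, with 22355 at an unadjusted p under 0.05, below chance.

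**Figure D3:**
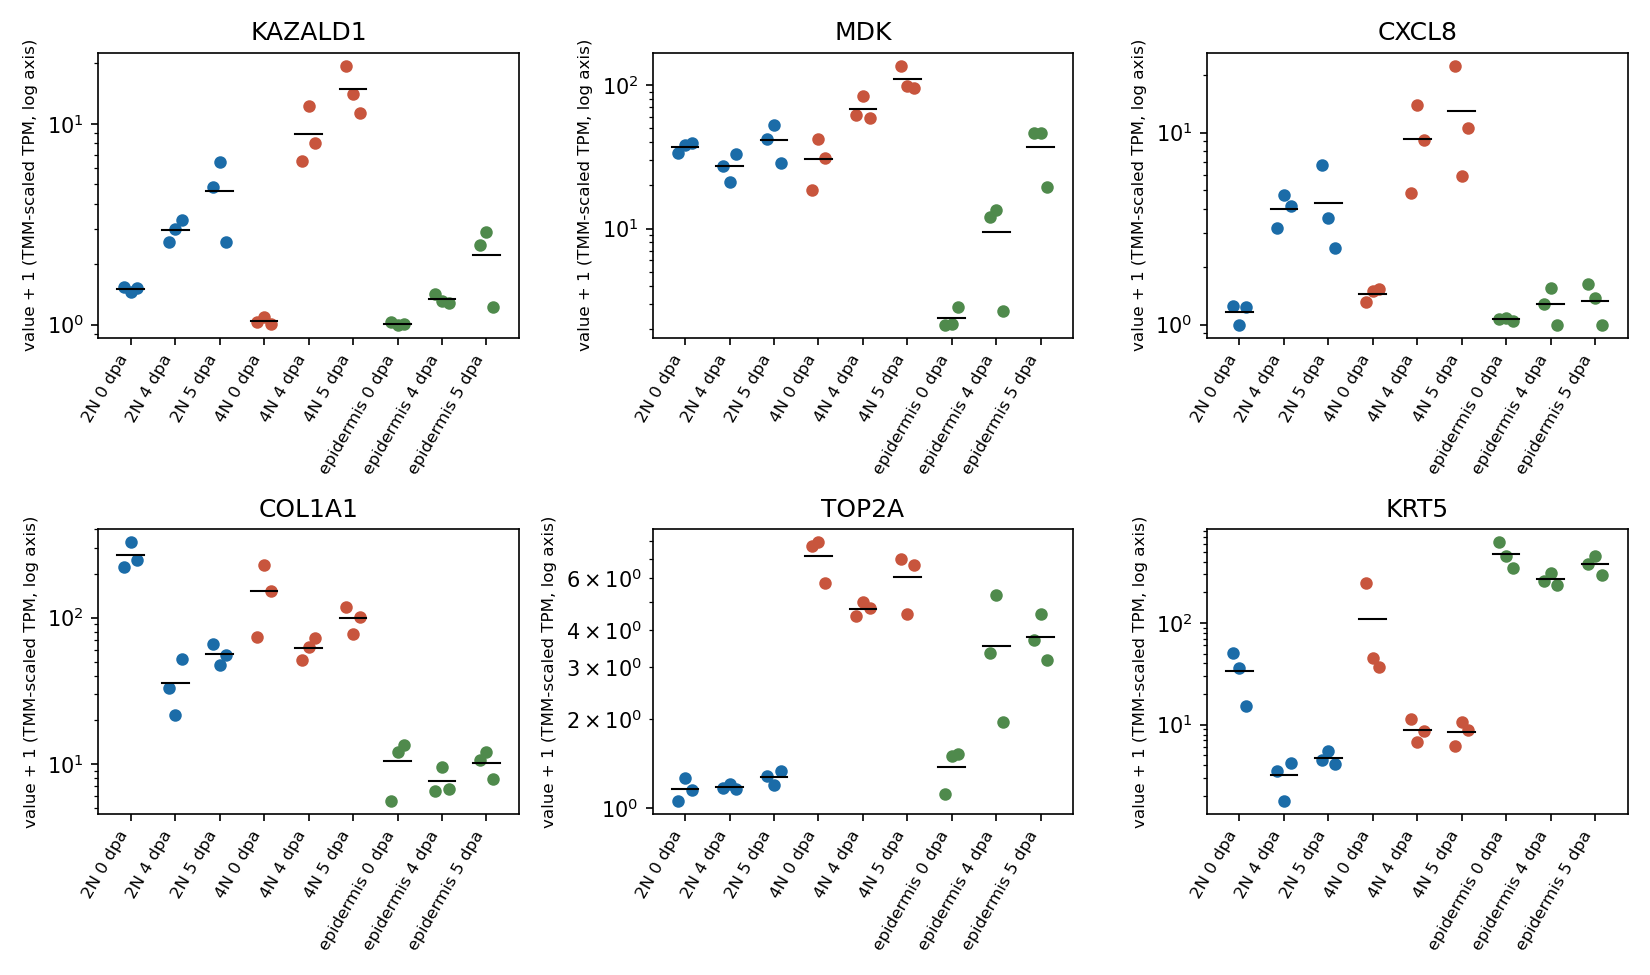
Signal of 6 named genes with 1 added, on a log axis, by group; points are libraries and bars are group means, n = 3. KAZALD1 has a mean signal of 14 in 4N cells at 5 dpa, COL1A1 one of 265 at 0 dpa and 34.5 at 4 dpa in 2N cells, and KRT5 in 4N cells at 0 dpa lies at 243, 44.3 and 35.5.

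The days 4 and 5 were compared within each fraction. Midkine had 36.4±15.5 against 8.4±5.85 in the epidermis (log2 change 2.19±0.43) and KAZALD1 14±4.11 against 7.93±2.97 in 4N cells (0.76±0.35). Neither was called (adjusted p = 0.136 and 1). COL1A1 was at 0.74±0.35 in 2N cells and 0.66±0.35 in 4N cells, also not called. The matrix list had a median of 0.35 in 2N cells (adjusted p = 3.96e-06), 0.26 in 4N cells (adjusted p = 1.85e-06) and 0.14 in the epidermis (adjusted p = 0.0347, and adjusted p = 0.147 with median-of-ratios rescaling). Limma called 0 of 35 members in any of them (1, 2 and 2 higher at an unadjusted p under 0.05). In 4N cells the growth factor list was at 0.27 (adjusted p = 0.000838), the leukocyte list at -0.16 (adjusted p = 0.00697) and the interferon list at -0.25 (adjusted p = 0.00972). Also called in 4N cells were epidermal markers (median -0.10, adjusted p = 0.00156), limb development (0.13, adjusted p = 0.0321, and adjusted p = 0.0506 with array weights) and erythrocyte genes (-0.51, adjusted p = 0.0489). The erythrocyte call ended with median-of-ratios rescaling (adjusted p = 0.0658), with the replicate block (0.0625) and without the 3 sparse libraries (0.0507). In 2N cells interferon genes had a median of -0.24 (adjusted p = 0.0264, and adjusted p = 0.0549 with array weights). In the epidermis DNA replication genes had a median of -0.46 (adjusted p = 3.15e-06). Limma called 0 transcripts in 2N and 4N cells, where 15684 and 17267 had an unadjusted p under 0.05, fewer than by chance. Without 4 dpa replicate 2 of the 2N cells the count was 2, and without 5 dpa replicate 2 of the 4N cells 3. In the epidermis it called 22, 10 higher and 12 lower. That count was 14 without 4 dpa replicate 3, 229 without 5 dpa replicate 2 and 5 without 5 dpa replicate 3, the library with the fewest transcripts. The named gene among these 22 was MUC5A, a mucin, with 0.978±1.24 against 23.9±24.8 (log2 change -3.35±0.51, adjusted p = 0.028). Its adjusted p was 0.0702 and 0.0591 without 4 dpa replicates 2 and 3 and 0.0928 and 0.167 without 5 dpa replicates 1 and 3, and 0.00663 to 0.903 over all alternatives.

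Transcripts called the same way at both days numbered 2975 in 2N cells (1261 higher and 1714 lower, against 30.7 for independent calls), 3757 in 4N cells (2912 and 845, against 98.8) and 74 in the epidermis (31 and 43, against 0.109). Both days share the 0 dpa libraries, so independent calls do not measure chance. The 10 simulations of unchanged groups, where few calls arise, gave 0 shared calls and decide nothing.

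Comparing 4N with 2N cells asked which transcripts are enriched in cells that have copied their DNA. At 0 dpa H1, a histone and so one of the proteins that package DNA, had 125±6.29 against 2.82±0.632 (33.3-fold, log2 difference 5.06±0.32, adjusted p = 3.57e-09), H2A 68.4±24.3 against 1.01±0.693 (34.1-fold, log2 difference 5.09±0.41, adjusted p = 2.19e-07) and HIST1H4A 40.3±8.83 against 0.933±0.168 (21.1-fold, log2 difference 4.40±0.35, adjusted p = 2.19e-07). TOP2A, which untangles DNA before mitosis, had 6.15±1.18 against 0.158±0.104 (log2 difference 2.62±0.31, adjusted p = 0.000166). NUSAP1, a spindle protein, had 3.3±0.621 against 0.10±0.0755 (log2 difference 1.96±0.30, adjusted p = 0.00224), while MKI67 was not called (log2 difference 1.24±0.30, adjusted p = 0.0533). The list of histones and chromatin proteins has 3 measured histones (HIST1H4A, H3F3A and H2AZ1) and 7 other proteins, and lacks H1, H2A, H2A2A, H2B12 and H3, which limma called at 0 dpa. In it 4 of 10 members were higher (8 adjusted over the list alone, adjusted p = 8.28e-08), and mitosis genes in 7 of 15 (13 adjusted over the list alone, adjusted p = 1.58e-16). Matrix genes had a median of -0.78, with 0 of 35 members called by limma (24 at an unadjusted p under 0.05) and 1 lower adjusted over the list alone (adjusted p = 8.21e-13). The medians were -0.56 for growth factor signalling (adjusted p = 0.00185), -0.15 for proteases (1 of 22 members lower and 0 higher (0 at an unadjusted p under 0.05), adjusted p = 0.00185), 0.36 for DNA replication (adjusted p = 0.0347, and adjusted p = 0.154 without the 3 sparse libraries) and 0.30 for epidermal markers (adjusted p = 0.0171). List counts moved without 1 library to mitosis genes higher 2 (2N replicate 2) or 3 (2N replicates 1 and 3 and 4N replicate 2), and proteases lower 0 (4N replicate 2). The epidermal share was up to 42.6% in the 4N and 10.3% in the 2N libraries.

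At 4 dpa H1 had 72.1±31.2 against 4.16±1.26 in 4N against 2N cells (log2 difference 3.77±0.32, adjusted p = 2.82e-06) and HIST1H4A 19.7±11 against 1.75±0.889 (log2 difference 2.83±0.35, adjusted p = 0.000979). At 5 dpa H1 had 68.1±31.8 against 4.75±1.48 (log2 difference 3.51±0.32, adjusted p = 1.37e-05) and H2A 34.8±3.58 against 2.06±1.38 (log2 difference 3.63±0.41, adjusted p = 0.000298). TOP2A was 3.73±0.257 against 0.18±0.0261 at 4 dpa (log2 difference 2.00±0.31, adjusted p = 0.0214). Each library of either group left out ended that call, with an adjusted p of 0.0525 to 0.123, and 0.00293 to 0.581 over all alternatives. At 5 dpa it was 5.06±1.32 against 0.272±0.0659 (log2 difference 2.23±0.31, adjusted p = 0.0045), and the call ended without 4N replicate 1 (adjusted p = 0.0538, and 0.00034 to 0.347 over all alternatives). Mitosis genes were higher in 1 of 15 members at 4 dpa (13 adjusted over the list alone, adjusted p = 9.58e-18) and in 1 at 5 dpa (12, adjusted p = 4.3e-16), counts that became 0 (any library) and 0 (4N replicate 1) without 1 library. In the list of histones and chromatin proteins, which lacks H1 and H2A, those higher were 1 of 10 (6, adjusted p = 6.03e-06) at 4 dpa and 1 at 5 dpa (6, adjusted p = 1.36e-05). With 0 members called by limma at either day (16 and 15 higher at an unadjusted p under 0.05), the matrix list was higher in 4N cells at 4 dpa (median 0.73, 13 of 35 adjusted over the list alone, adjusted p = 9.42e-09) and 5 dpa (0.59, 9, adjusted p = 1.47e-07). Leukocyte markers were lower in 4N cells at 4 dpa (median -0.65, 8 of 30 adjusted over the list alone, adjusted p = 5e-10) and 5 dpa (-0.86, 22, adjusted p = 3.37e-12), with 0 called by limma over all transcripts (17 and 25 lower at an unadjusted p under 0.05).

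With 0 of 10 members called by limma at either day (3 and 2 higher at an unadjusted p under 0.05), DNA replication genes had medians of 0.34 at 4 dpa (adjusted p = 0.00486) and 0.30 at 5 dpa (adjusted p = 0.0169). Epidermal markers had 0.24 at 4 dpa (adjusted p = 0.0439). The limb development list had a median difference of 0.59 at 4 dpa (adjusted p = 0.00297) and 0.41 at 5 dpa (adjusted p = 0.00528). Growth factor signalling had 0.35 (adjusted p = 0.00527) and 0.52 (adjusted p = 0.000163). KAZALD1, MDK and PRRX1 were not called between 4N and 2N cells at 5 dpa (log2 difference 1.76±0.35, adjusted p = 0.0696, log2 difference 1.45±0.43, adjusted p = 0.343, and log2 difference 0.52±0.27, adjusted p = 0.874). Histone transcripts of one family can share reads, which the files do not resolve.

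Limma called 2752 transcripts between 4N and 2N cells at 0 dpa (552 higher and 2200 lower in 4N), 54 at 4 dpa (39 and 15), and 78 higher and 40 lower at 5 dpa. The 0 dpa count was 5012 without the 3 sparse libraries, 3722 higher and 1290 lower, which turns the balance. It was 1244 without 2N replicate 2 and 7018 without 4N replicate 1. Of the calls 36.5%, 44.3% and 42% were higher in 4N without 4N replicates 1, 2 and 3, against 20.1% with all. At 4 dpa it was 18, 29 and 15 without 2N replicates 1, 2 and 3 and 13 and 23 without 4N replicates 1 and 2. At 5 dpa it was 34, 30 and 65 without the 2N and 23, 54 and 70 without the 4N replicates. With only the 6 libraries of a day in the model limma called 0, 0 and 0, with 33398, 33001 and 39743 at an unadjusted p under 0.05.

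4N stump cells were also compared with the wound epidermis of the same day. At 4 dpa COL3A1, a collagen of loose connective tissue, had 48.4±10.3 against 2.04±0.85 in 4N cells against epidermis (16.4-fold, log2 difference 4.03±0.34, adjusted p = 4.3e-07). MDK had 67.4±13.7 against 8.4±5.85 (log2 difference 3.16±0.43, adjusted p = 4.83e-05) and KAZALD1 7.93±2.97 against 0.343±0.0736 (log2 difference 2.68±0.35, adjusted p = 3.02e-05). KRT5 had 7.96±2.34 against 267±37 (log2 difference -4.93±0.48, adjusted p = 1.78e-06) and MPEG1, a pore-forming protein of macrophages, 2.29±1.52 against 59±14.8 (log2 difference -4.27±0.44, adjusted p = 2.81e-06). At 5 dpa BGN, a matrix proteoglycan, had 14.6±1.74 against 0.575±0.228 (log2 difference 3.31±0.34, adjusted p = 1.65e-06) and PRRX1 1.67±0.333 against 0.0667±0.0804 (log2 difference 1.32±0.27, adjusted p = 0.00345). IL11 had 8.3±4.38 against 0.0897±0.0798 (log2 difference 3.00±0.31, adjusted p = 1.76e-06) and KRT5 7.51±2.21 against 375±75.9 (log2 difference -5.48±0.48, adjusted p = 2.99e-07). Of 35 matrix genes 28 were higher in 4N cells at 4 dpa and 26 at 5 dpa (31 and 32 adjusted over the list alone, adjusted p = 2.43e-20 and 1.37e-19). Epidermal markers were lower in 30 of 33 members at both days (31 adjusted over the list alone, adjusted p = 1.75e-11 and 2.08e-11).

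Higher in 4N cells than in the epidermis as lists were growth factor signalling (5 of 9 higher and 0 lower at 4 dpa, 7 and 1 at 5 dpa; medians 1.26 and 1.58; adjusted p = 0.000242 and 0.000459), limb development and blastema (2 of 5 higher and 0 lower at 4 dpa, 3 and 0 at 5 dpa; medians 0.84 and 0.84; adjusted p = 0.00513 and 0.00662), proteases and inhibitors (8 of 22 higher and 0 lower at 4 dpa, 7 and 0 at 5 dpa; medians 0.77 and 0.68; adjusted p = 1.49e-06 and 2.38e-06) and leukocyte markers (2 of 30 higher and 1 lower at 4 dpa, 1 and 1 at 5 dpa; medians 0.35 and 0.26; adjusted p = 0.000688 and 0.0128). With 1 library left out the 4 dpa counts moved to limb development 1 (epidermis replicate 1 and 4N replicate 2), proteases 5 (4N replicate 3), and leukocytes 1 (any but 4N replicate 1), and the 5 dpa leukocytes to 0 (epidermis replicate 3 and 4N replicates 2 and 3). Lower was the interferon list, with 6 of 17 members at 4 dpa and 9 at 5 dpa, where it was 5 (epidermis replicate 1) without 1 library (adjusted p = 0.0471 and 0.0317). The 4 dpa call ended with median-of-ratios rescaling (adjusted p = 0.0567) and both ended without the 3 sparse libraries (adjusted p = 0.105 and 0.0923) and with array weights (0.144 and 0.0736). Mitosis genes had medians of 0.02 and 0.32 with 0 of 15 called by limma at either day (0 and 1 higher at an unadjusted p under 0.05; adjusted p = 0.246; at 5 dpa adjusted p = 0.0244, and adjusted p = 0.0965 without the 3 libraries and 0.089 with array weights).

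Limma called 18741 transcripts between 4N cells and epidermis at 4 dpa (7359 higher and 11382 lower in 4N) and 22345 at 5 dpa (11308 and 11037), the latter 23686 (8221 and 15465) without the 3 sparse libraries. The 4 dpa count was 12114 without epidermis replicate 1 and 12445 and 10886 without 4N replicates 1 and 2, and the 5 dpa count 13229 and 14790 without 4N replicates 1 and 3. With only the 6 libraries of a day in the model limma called 5875 and 3250.

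Whether the change since 0 dpa differed between 4N and 2N cells was tested directly. COL1A1 had a log2 change of -1.15±0.35 in 4N and -2.97±0.35 in 2N cells at 4 dpa, a difference of 1.83±0.49 that was not called itself (adjusted p = 0.151). The matrix list had a median difference of 1.55 at 4 dpa (30 of 35 members higher adjusted over the list alone and 0 over all transcripts by limma (30 at an unadjusted p under 0.05), adjusted p = 2.63e-19) and 1.40 at 5 dpa (29 and 1, adjusted p = 3.24e-18). It rests on 4N libraries of 0 dpa of which replicate 1 stood at 42.6% of the epidermal level and replicates 2 and 3 held few transcripts. Without the 3 libraries the epidermal list was lower in the same test (adjusted p = 0.00149 and 0.000291). The matrix count without 1 library was 2 (4N 0 dpa replicate 2) at 4 dpa and 0 or 4 (any but 4N 0 dpa replicate 3) at 5 dpa. Growth factor signalling had 0.87 (4 of 9 adjusted over the list alone, adjusted p = 3.01e-05) and 1.19 (7, adjusted p = 7.98e-07). Limb development had 0.58 (adjusted p = 0.00522) and 0.64 (adjusted p = 0.00806). Proteases had 0.40 at 4 dpa (adjusted p = 0.0359). Leukocyte markers had medians of -0.80 (0 of 30 lower by limma adjusted over the list alone and 12 at an unadjusted p under 0.05, adjusted p = 5.76e-06) and -0.96 (13, adjusted p = 1.24e-07). TNC differed by 2.31±0.61 at 4 dpa and 2.45±0.61 at 5 dpa and KAZALD1 by 2.09±0.49 and 2.30±0.49. Their adjusted p was from 0.0637 to 0.143.

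The called named genes were EMILIN1, a glycoprotein of elastic fibres, and the zinc finger gene ZN224, at 5 dpa. EMILIN1 had 6.01±1.29 against 1.91±0.44 in 4N and 1.85±0.619 against 3.43±0.43 in 2N cells (log2 difference 1.93±0.38, adjusted p = 0.0384). ZN224 had 13.7±0.653 against 1.0±0.958 and 6.14±2.08 against 11.4±5.14 (log2 difference 3.72±0.73, adjusted p = 0.0406). Both calls ended with median-of-ratios rescaling (adjusted p = 0.0695 and 0.0534). Leaving out any of the 12 libraries except 4N 0 dpa replicates 2 and 3 ended the EMILIN1 call (adjusted p = 0.0501 to 0.132). Leaving out any except 2N 0 dpa replicate 3 and 4N 0 dpa replicate 3 ended the ZN224 call (0.0501 to 0.128). Over all alternatives their adjusted p was 0.00972 to 0.325 and 0.0153 to 0.293. Limma called 367 transcripts at 4 dpa, 351 higher and 16 lower in the 4N change, and 465 at 5 dpa, 438 and 27. Without the 3 sparse libraries the counts were 1848 (881 and 967) and 1963 (846 and 1117). Without 1 library the 4 dpa count was 145 or 103 (2N 4 dpa replicates 2 and 3), 229 (2N 4 dpa replicate 1), 800, 583 or 702 (4N 0 dpa replicates 1, 2 and 3) or 139 (4N 4 dpa replicate 2). The 5 dpa count was 272 or 303 (2N 0 dpa replicates 1 and 2), 178, 211 or 102 (2N 5 dpa), 852 (4N 0 dpa replicate 1) or 120 or 207 (4N 5 dpa replicates 1 and 3). With only the 12 libraries of the test in the model limma called 0 and 0, with 36170 and 36369 at an unadjusted p under 0.05.

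**Figure D4:**
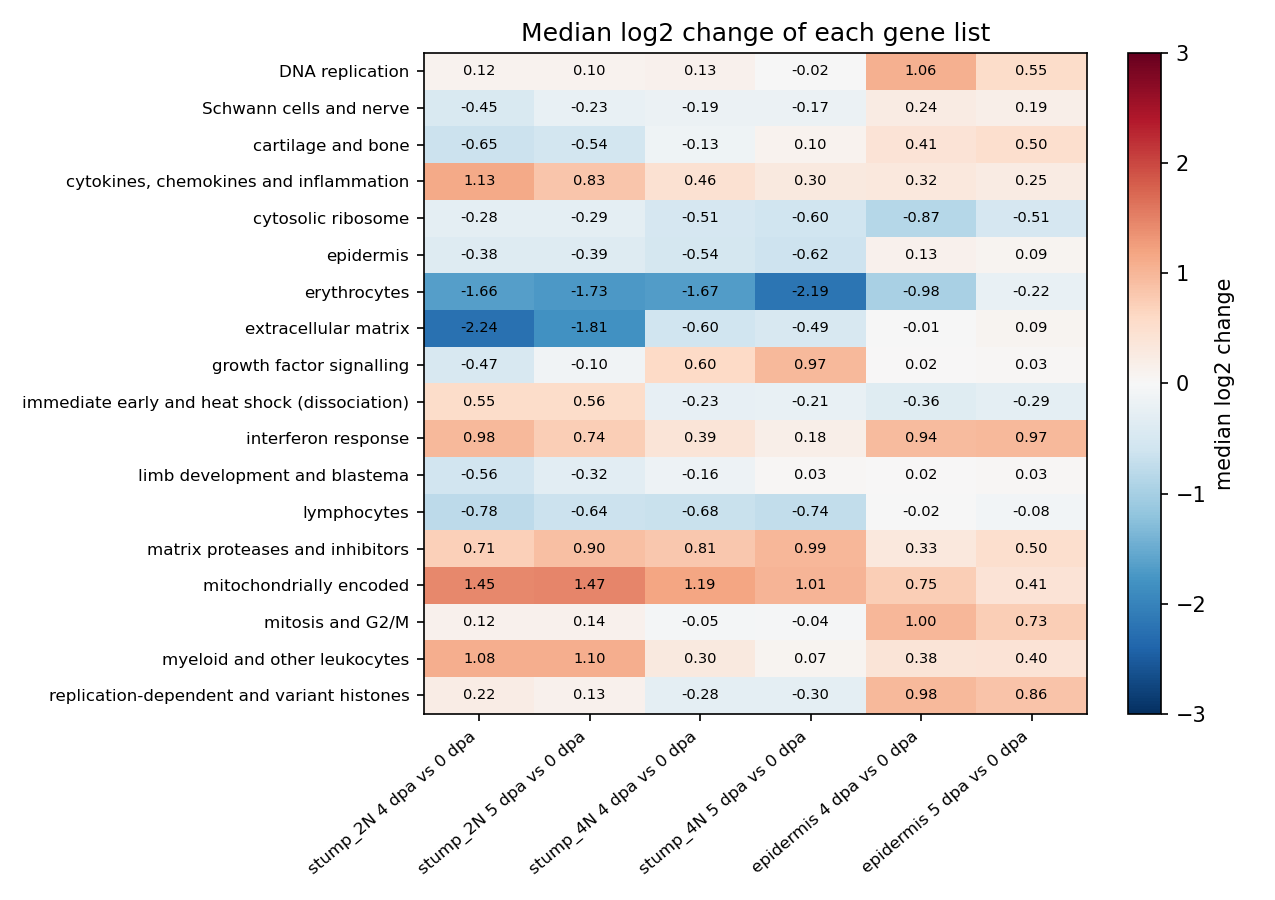
Median log2 change of the measured members of each of 18 gene lists since 0 dpa in 2N cells, 4N cells and epidermis, as printed in each field and on a colour scale from lower (blue) to higher (red). Matrix genes lie at -2.24 in 2N cells at 4 dpa and at -0.60 in 4N cells, and none of these lists passes with an estimated correlation.

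Transcripts enriched in 4N stump cells over both other fractions were counted at 4 and 5 dpa. At 5 dpa the named gene among them was TNC, with 2 transcripts at log2 differences of 2.00 and 1.60 over 2N cells (adjusted p = 0.0451 and 0.0491) and 3.12 and 2.40 over the epidermis (6.37e-06 and 1.23e-05). Each library of either stump group left out ended both calls over 2N cells, with an adjusted p of 0.0866 to 0.239. Over all alternatives it was 0.00286 to 0.686 and 0.00485 to 0.853. The count was 24 at 4 dpa, where independent calls give 0.57 and none had a protein name, and 66 at 5 dpa against 1.77. With 1 library left out it was 8, 7 and 5 (2N 4 dpa replicates 1, 2 and 3), 5, 14 and 53 (4N 4 dpa). At 5 dpa it was 39 (epidermis replicate 1), 16, 15 and 9 (2N) and 10 and 33 (4N replicates 1 and 2). The 5 dpa count was 225 without the 3 sparse libraries. With only the libraries of 1 day in the model both counts were 0 by limma. There 33001 and 39743 had an unadjusted p under 0.05 (4N against 2N).

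Changes shared by all 3 fractions were led by PLBL1, with log2 changes at 4 dpa of 5.59 in 2N cells, 4.00 in 4N cells and 3.52 in the epidermis. MT-CO1 rose in all 3 as well. These genes were picked out after their values were seen. The count was 54 at 4 dpa, 53 higher and 1 lower, where independent calls give 0.0509, and 4 at 5 dpa, with PLBL1 and MMP18 among them, against 0.00629. The MMP18 call in the epidermis at 5 dpa (adjusted p = 0.0447) ended without any 1 of its 6 libraries (adjusted p up to 0.196, and 0.00755 to 0.841 over all alternatives). Without 1 library the 4 dpa count was 8 (0 dpa epidermis replicate 1), 7 or 20 (4 dpa epidermis replicates 1 and 3) or 28 (4N 4 dpa replicate 3). The 5 dpa count was 2 without 0 dpa epidermis replicates 1 or 2, 5 dpa epidermis replicate 1, 2N 0 dpa replicates 1 or 3, or 4N 5 dpa replicates 2 or 3, and 7 without 0 dpa epidermis replicate 3 or 4N 0 dpa replicates 1 or 3. The counts were 75 and 8 without the 3 sparse libraries.

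The authors' deposited tables were compared with these calls. Of the transcripts in the authors' deposited table for 2N cells at 4 dpa, 9598 were tested here, 100% had the same direction and 45.9% were called. In the authors' deposited tables for 4N cells and epidermis at 4 dpa it was 100% in each, with 60.8% and 16.3% called, and at 5 dpa 100%, with 35.6%, 64.7% and 7.12% called for 2N cells, 4N cells and epidermis. The authors' deposited table of dividing-cell transcripts lists 298, of which 155 were tested here. Of these 100% were higher in 4N than in 2N cells at 4 and at 5 dpa and 43.2% at 0 dpa, with 0 called by limma at 4 dpa and 2 at 5 dpa. Both analyses use the same libraries, so equal directions are not independent evidence.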

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

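Of the tests in this part, those of the excess of rises without both 0 dpa 4N libraries, the same over transcripts lower in the epidermis, that of the authors' scaling, and those of epidermal transcripts scarce in 2N cells at 0 dpa were chosen only after the result was seen, as was leaving out the 3 sparse libraries.

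The change since 0 dpa differed between 4N and 2N cells, by the test of the difference itself, in 367 transcripts at 4 dpa and 465 at 5 dpa. Of 100 regroupings of the libraries 5 gave as many at 4 dpa, so that chance is not excluded there, and 3 at 5 dpa, a share under 0.05. Such regroupings mix groups that differ, so chance is not excluded at 5 dpa either. The highest of the other regroupings gave 4305 and 1483, several times the real counts. This points to a structure of the samples, and as the regroupings mix days and fractions, the differences between these can be that structure. Without the 3 sparse libraries the counts were 1848 and 1963, without any 1 library they were 103 to 800 and 102 to 852, and with only these 12 libraries in the model limma called 0 at each day (36170 and 36369 at an unadjusted p under 0.05). ZN224 differed by 3.72 and EMILIN1 by 1.93 at 5 dpa, and both calls ended in 10 of the 12 models that leave out 1 library. By camera, the lists that differed at 4 dpa had medians of 1.55 (extracellular matrix), 0.874 (growth factor signalling), 0.577 (limb development and blastema), 0.404 (matrix proteases) and -0.803 (leukocytes). At 5 dpa they had 1.4 (extracellular matrix), 1.19 (growth factor signalling), 0.642 (limb development and blastema) and -0.965 (leukocytes). With an estimated correlation their adjusted p was 0.0632 to 0.727. These medians rest on 4N libraries of 0 dpa with few transcripts (replicates 2 and 3) or 42.6% of the epidermal level (replicate 1), and without the 3 libraries the epidermal list was lower too (adjusted p = 0.00149 and 0.000291).

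In 4N cells 81% of the calls at 4 dpa were rises, while 2 of the 3 libraries of 0 dpa held few transcripts, and 3 tests were made of whether those libraries made the excess. Without both, 25.4% of the calls were rises, and 43.3% over transcripts lower in the epidermis than in 2N cells at 0 dpa. Without the 5 dpa epidermis library with few transcripts as well, these were 26.8% and 46.8%. The other test, whether 0 dpa replicate 1 lay at or above the lowest 4 dpa library, held for 0.375% of called rises. This met the bound written against this explanation. Calling favours rises with low controls, which can lower the value, a reason given only after the value was seen. The lone remaining control has no replicate and carries 42.6% of the epidermal level, so fewer caught transcripts may make up the excess and cannot be told apart from a rise of transcripts in dividing cells, which was not tested. The tables argue against the authors' scaling as the whole cause, with 70.7% rises after median-of-ratios rescaling. The authors' deposited table for the same libraries has 3283 higher and 2529 lower, a smaller excess, and why it is smaller was not tested.

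Transcripts abundant in the epidermis were lower in both stump fractions after amputation. Fewer transcripts in the 4N libraries of 0 dpa are argued against as the whole cause, since 100% of 10 such transcripts scarce in 2N cells at 0 dpa, a choice that works against a fall, were lower in 2N cells at 4 dpa as well (median -1.85, 2 called), where no library had few. Epidermal cells in the stump samples of 0 dpa may account for it, since 100% of these 10 were lower in 4N cells at 4 dpa (median -1.54, 4 called; without the 3 sparse libraries -3.35 and 6, where the remaining 0 dpa control is the one at 42.6%), and the DNA content gate does not remove such cells. KRT5 stood at 243, 44.3 and 35.5 in the 4N libraries of 0 dpa, and these libraries held 42.6%, 4.36% and 9.0% of the epidermal level. Of 19 transcripts scarce in the other stump fraction at 5 dpa 100% were lower in 4N cells (median -2.04, 10 called) and 100% in 2N cells, but that choice favours a fall, so nothing is read from it. A fall of these transcripts within stump cells would give the same values, stays open and was not tested.

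In 2N cells at 4 dpa limma called 25 of 35 matrix genes lower and 13 of 30 leukocyte genes higher (without 1 library 7 (0 dpa replicate 2) or 8 (4 dpa replicates 2 and 3)), and neither list passed with an estimated correlation (adjusted p = 0.558 for both). If more leukocytes thinned out all other cells alike, matrix genes leukocytes lack would share 1 change. At 4 dpa 31.6% of 19 tested members lay over 2 SE from their median. Leukocytes may make some (not tested), so thinning stays open. A shift of the scaling is argued against, since with median-of-ratios rescaling the medians stayed apart, and the one nearer to 0 was 1.06. More leukocytes together with a lower output of matrix genes in stump cells could give both changes, a hypothesis that was not tested.

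The libraries were also split in other ways. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each of the comparisons of days with 0 dpa. The real count and the highest of the other splits were 7283 against 6 for 2N cells at 4 dpa and 3910 against 2 at 5 dpa, 7236 against 49 and 8967 against 21 for 4N cells, and 654 against 7 and 152 against 19 for the epidermis. Likewise 1 of 10 gave as many for 4N against 2N cells, with 2752 against 343 at 0 dpa, 54 against 1 at 4 dpa and 78 rises and 40 falls against 2 calls at 5 dpa, and for 4N cells against epidermis, with 18741 against 1 and 22345 against 0. Between 5 and 4 dpa 10 of 10 splits gave as many in 2N cells (0 against 1) and 4N cells (0 against 5) and 3 of 10 in the epidermis (22 against 104), where a split several times above the real count points to a structure of the samples. For combined counts 100 regroupings were drawn. Of these 1, the real one, gave as many transcripts higher in 4N cells than in both others at 4 dpa (24 against 10). At 5 dpa 2 did (66 against 110). These counts fell to 5 and 9 without 1 library. With only the libraries of that day in the model they were 0 by limma (33001 and 39743 differed between 4N and 2N cells at an unadjusted p under 0.05). For changes shared by all 3 fractions it was 1 at each day (54 against 0 and 4 against 0). Regroupings mix differing fractions or days, so chance is not excluded.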

How the results depend on the processing

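The filter of at least 5, limma array weights and leaving out the 3 libraries with the fewest transcripts, or only the 4N libraries among them, were chosen after seeing the data, and the other alternatives were planned. All of them were run. Counts that stayed within 1.5 times are not repeated here, and the calls counted are those of limma at an adjusted p of 0.05 unless camera is named. Read depth is unknown, so no limit that depth sets can be given. Where a cause is not stated, the cause was not tested.

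With only the groups compared in the model, which leaves fewer samples and takes no spread from other groups, the counts were 40 for 2N cells at 4 dpa. They were 5875 and 3250 for 4N against epidermis at 4 and 5 dpa, and 19 for all 3 fractions at 4 dpa. They were 0 for 2N cells at 5 dpa, for 4N cells and epidermis at 4 and 5 dpa and for epidermis at 5 against 4 dpa. They were also 0 for 4N against 2N at 0, 4 and 5 dpa. At 4 and 5 dpa they were 0 for the 4N minus the 2N change and for higher in 4N than in both others. Where limma called 0, 16634 to 51822 had an unadjusted p under 0.05, the lowest below chance. Of 163 genes the rule ranked first 40 kept their call. Without the 3 libraries with the fewest transcripts they were 10 for epidermis at 5 against 4 dpa, 5012 for 4N against 2N at 0 dpa, 1848 for the 4N minus the 2N change at 4 dpa, 1963 for the 4N minus the 2N change at 5 dpa, 225 for higher in 4N than in both others at 5 dpa and 8 for all 3 fractions at 5 dpa, and without only both 4N libraries of 0 dpa among these 4318 for 4N cells at 4 dpa, 5231 for 4N cells at 5 dpa, 984 for the 4N minus the 2N change at 4 dpa and 1066 for the 4N minus the 2N change at 5 dpa. Each replicate left out in turn, which also leaves fewer samples, gave 3433 to 5617 for 2N cells at 4 dpa, 1684 to 2991 for 2N cells at 5 dpa, 3151 to 11629 for 4N cells at 4 dpa, 4033 to 13185 for 4N cells at 5 dpa, 128 to 969 for epidermis at 4 dpa, 49 to 602 for epidermis at 5 dpa, 0 to 2 for 2N cells at 5 against 4 dpa, 0 to 3 for 4N cells at 5 against 4 dpa, 5 to 229 for epidermis at 5 against 4 dpa, 1244 to 7018 for 4N against 2N at 0 dpa, 13 to 69 for 4N against 2N at 4 dpa, 23 to 70 for 4N against 2N at 5 dpa, 10886 to 13906 for 4N against epidermis at 4 dpa, 13229 to 19660 for 4N against epidermis at 5 dpa, 103 to 800 for the 4N minus the 2N change at 4 dpa, 102 to 852 for the 4N minus the 2N change at 5 dpa, 5 to 53 for higher in 4N than in both others at 4 dpa, 9 to 77 for higher in 4N than in both others at 5 dpa, 7 to 66 for all 3 fractions at 4 dpa, 2 to 7 for all 3 fractions at 5 dpa, and 154 to 163 of 163 named genes not seen to lose their call, where genes of comparisons without the left-out library were not refitted.

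A filter of at least 5 in 3 libraries, under which fewer transcripts were tested, gave 3374 for 2N cells at 4 dpa, 1874 for 2N cells at 5 dpa, 4214 for 4N cells at 4 dpa, 3783 for 4N cells at 5 dpa, 66 for epidermis at 5 dpa, 1 for epidermis at 5 against 4 dpa, 694 for 4N against 2N at 0 dpa, 21 for 4N against 2N at 4 dpa, 19 for 4N against 2N at 5 dpa, 8584 for 4N against epidermis at 4 dpa, 10051 for 4N against epidermis at 5 dpa, 148 for the 4N minus the 2N change at 4 dpa, 164 for the 4N minus the 2N change at 5 dpa, 8 for higher in 4N than in both others at 4 dpa, 4 for higher in 4N than in both others at 5 dpa, 137 for all 3 fractions at 4 dpa and 10 for all 3 fractions at 5 dpa. With no filter, under which more were tested, the counts were 7372 for 2N cells at 5 dpa, 2170 for epidermis at 4 dpa, 1126 for epidermis at 5 dpa, 168 for 2N cells at 5 against 4 dpa, 404 for 4N cells at 5 against 4 dpa, 351 for epidermis at 5 against 4 dpa, 5409 for 4N against 2N at 0 dpa, 424 for 4N against 2N at 4 dpa, 1082 for 4N against 2N at 5 dpa, 911 for the 4N minus the 2N change at 4 dpa, 1104 for the 4N minus the 2N change at 5 dpa, 95 for higher in 4N than in both others at 4 dpa, 229 for higher in 4N than in both others at 5 dpa and 31 for all 3 fractions at 4 dpa. A pseudocount of 0.1 gave 2821 and 1053 for 2N cells at 4 and 5 dpa, 11014 for 4N cells at 4 dpa, 75 and 68 for epidermis at 4 and 5 dpa and 0 at 5 against 4 dpa. At 4 and 5 dpa it gave 10 and 9 for 4N against 2N, 99 and 9 for the 4N minus the 2N change, 0 and 0 for higher in 4N than in both others and 17 and 8 for all 3 fractions. Array weights gave 11982 and 8177 for 2N cells, 988 and 1680 for 4N cells and 1631 and 297 for epidermis at 4 and 5 dpa. At 5 against 4 dpa they gave 3 for 2N and 12 for 4N cells. For 4N against 2N they gave 138, 536 and 1596 at 0, 4 and 5 dpa, and 29655 for 4N against epidermis at 4 dpa. At 4 and 5 dpa they gave 56 and 99 for the 4N minus the 2N change and 279 and 878 for higher in 4N than in both others. For all 3 fractions at 5 dpa they gave 11. Median-of-ratios rescaling gave 74 for 4N against 2N at 5 dpa, 305 for the 4N minus the 2N change at 5 dpa, 15 for higher in 4N than in both others at 4 dpa and 41 for higher in 4N than in both others at 5 dpa, and sums over the transcripts of 1 gene gave 14 for epidermis at 5 against 4 dpa.

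The replicate number as a block gave 11 for epidermis at 5 against 4 dpa, 34 for 4N against 2N at 4 dpa, 42 for higher in 4N than in both others at 5 dpa and 7 for all 3 fractions at 5 dpa. The libraries share a number and no stated origin. Of 108 same-number pairs between groups, days pooled, 26 had an r over 0.1 (median 0.012, -0.267 to 0.399, across transcripts). A same-day pairing was not tested. As a hint from the data, 17 of 27 libraries correlated best with their own number, where chance gives 9, so a shared origin of some libraries stays open. The calls that ended with the block are not evidence of smaller effects.

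Among calls of single genes, 296 ended with only the groups compared, 56 with a pseudocount of 0.1, 45 with array weights, 44 without the 3 libraries, 47 without only both 4N libraries of 0 dpa, 29 with no filter, 14 with sums over transcripts, 13 with the replicate block, 10 with median-of-ratios rescaling and 3 with the filter of at least 5. Of the calls refitted without 1 library, 4 to 23 ended per library, among them 20 of 35 without 0 dpa epidermis replicate 1. DKK1 in 4N cells at 5 dpa turned its direction with sums over transcripts, from a log2 change of 1.23 to -0.24 (adjusted p = 0.568). Of the 94 list calls by camera, 0 passed with an estimated correlation, 12 ended without the 3 libraries, 22 with fry, 7 with array weights, 3 with median-of-ratios rescaling and 1 with the replicate block. Lists not called with all libraries but called without the 3, besides those given for 4N cells, were epidermal markers for the 4N minus the 2N change at 4 dpa (0.00149), epidermal markers for the 4N minus the 2N change at 5 dpa (0.000291), proteases for the 4N minus the 2N change at 5 dpa (0.00478), limb development for 4N against 2N at 0 dpa (0.042), cytokines for 4N against 2N at 4 dpa (0.0416), epidermal markers for 2N cells at 4 dpa (0.0453), limb development for 2N cells at 5 against 4 dpa (0.0272). The limb development list of 2N cells at 5 against 4 dpa was also called with the replicate block (0.0462).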

Other observations

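The genes given here were picked by hand after their values were seen. TGM3, a transglutaminase that hardens the outer skin, had 2.1 ± 0.551 against 64 ± 26.1 in 4N cells against epidermis at 4 dpa (log2 difference -4.33 ± 0.41, adjusted p = 1.36e-06). Higher in 4N cells were SFRP2, a secreted modulator of Wnt signalling, with 4.28 ± 1.44 against 0.205 ± 0.086 at 5 dpa (log2 difference 2.10 ± 0.38, adjusted p = 0.000902), TIG1, a gene that responds to retinoic acid, with 13.3 ± 2.4 against 0.483 ± 0.0503 (log2 difference 3.26 ± 0.33, adjusted p = 1.49e-06), and TGFBI, a matrix protein, with 14.9 ± 1.82 against 3.88 ± 1.3 (log2 difference 1.74 ± 0.29, adjusted p = 0.000443).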
